A study of Mus musculus with 8 samples.

How the data were processed

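Mouse haematopoietic stem and progenitor cells were sorted from bone marrow as LSK cells (lineage-negative, Sca-1-positive, c-Kit-positive) and grown on OP9-DL1, a stromal line that carries the Notch ligand Delta-like 1 and drives progenitors towards the T lineage in culture. Per the labels' protocols, the donors carried a tamoxifen-inducible Cre together with either wild-type or floxed Tcf7 and Lef1 alleles, 4-hydroxytamoxifen was given on days 3 to 5, and c-Kit-positive DN1 cells, the earliest CD4-negative, CD8-negative stage, gated as CD44-high and CD25-negative, were sorted on day 7. Tcf7 and Lef1 encode the transcription factors TCF1 and LEF1. The 8 libraries comprise 4 of RNA and 4 from ATAC-seq, which marks open chromatin by the insertions of a transposase, with 2 control and 2 Tcf7/Lef1 knockout libraries for each assay. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates came from separate animals or cultures. The p-values of single genes therefore rest on the spread between these libraries, pooled across genes, which may be technical. Those of gene lists with a preset correlation, and of all tests on regions, compare genes or regions with one another. They do not measure the spread between replicates.

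RNA reads were aligned with HISAT2 and gene abundances estimated with StringTie on the mm10 build, per the submitters' processing notes, which give no versions. The deposited TPM column (transcripts per 1000000) sums to 1000000 in each library, per the file headers and the values. The deposited FPKM column (scaled to transcript length and library size) is the authors' value before the scaling to TPM and was used only as an alternative. The deposited coverage column is an unscaled signal per base, and was used only for its ratio to FPKM, whose most common value in a library follows that library's sequencing depth. That ratio was 2.412 and 2.122 in the control libraries and 2.638 and 2.63 in the knockout libraries, so relative depth spanned a narrow range. Read counts were not used here, so no counting error per gene could be given. A gene ID with several entries in a library had its TPM summed. Whether the authors' quantification used strand is not given in the sources used here, and reads of near-identical copies, such as Mcpt1 and Mcpt2, may have been split between them.

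ATAC reads were aligned with Bowtie2 and peaks called with MACS2 on mm10, per the submitters' processing notes. Each library has a list of its own, so the authors did not pool replicates for these files. The deposited lists have the narrowPeak layout, in which the authors' peak caller gives a fold enrichment (a ratio over local background) and the −log10 p and −log10 q of each peak. The lowest −log10 q was between 2.74 and 2.87 across the lists. Thresholds, duplicate removal and any shift of reads for the transposase are not given in the sources used here. Peak lists carry no read counts, so ATAC depth is unknown and no test between ATAC libraries was made.

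RNA was compared on log2(TPM + 1) with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, over 13228 genes with a mean TPM of at least 1, with genotype as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes on this scale understate the change of low genes, so folds between mean TPM are also given. On simulated libraries with the real means of these 13228 genes, changes were made on the log2(TPM + 1) scale and kept at 0 or above. The same code recovered 94% of 100 genes changed by 1 and 97% of 100 changed by 2, with 6 unchanged genes called. For low genes such changes are larger folds in TPM. The simulated spread followed the trend with expression only, so real genes with a wider spread may be recovered less often. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over 16 lists, and again with an estimated correlation. The second form takes its correlation and its degrees of freedom from the residuals. These had 2 degrees of freedom here, so it had little power to call any list. The tests, the lists, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined. Those 2, chosen after the data were seen, were TPM rescaled without Rpph1, an abundant non-coding RNA, and changes centred on their median. The lists covered T-lineage, Notch target, stem and progenitor, myeloid, B-lineage, NK and innate lymphoid, dendritic cell, mast cell and basophil, erythroid and megakaryocyte, stromal, gamma-delta T, cell cycle, p53 target, Wnt target, interferon response and handling stress genes, with Tcf7 and Lef1 left out of all. A further 4 lists, of hypoxia-response, adipocyte, NF-kappaB target and ribosome biogenesis genes, were written after the data were seen. Named genes were Tcf7 and Lef1, the 10 largest falls and 10 largest rises among called genes with named models and non-overlapping replicates, and up to 4 called members of each list with the largest change; others are said to have been chosen after their values were seen. Not every gene that this rule names is reported here.

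ATAC peaks of the 4 lists were merged into 134830 union regions wherever they shared at least 1 bp, with the mitochondrial chromosome left out; bedtools 2.31.1 gave the same number. A region was open in control alone when both control lists and neither knockout list held a peak in it, and open in knockout alone in the converse case. The level without a genotype difference was taken from the pairs made of a control and a knockout library. Each region was assigned to the nearest gene start within 50 kb, with gene starts from the deposited RNA tables, which use the same build. Links between RNA and regions were tested with two-sided Fisher's exact tests over 6 comparisons, with Benjamini-Hochberg adjustment, and by 100000 permutations of gene labels within strata of the number of regions per gene. That number counts every region assigned to a gene, the control-alone and knockout-alone ones included, so the strata also take out part of a difference in those. On simulated lists all 50 regions made for the control-alone or knockout-alone class were recovered, and a simulated odds ratio of 3 was returned as 2.94. Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 were used. Tests of each gene list against the region classes (40 in all, adjusted together) were added after the data were seen. The planned search for TCF/LEF motifs needs the genome sequence, which was not used here. Alternatives covered the pseudocount, the filter on low values, the scaling, the variance model, each library left out, the replicate number as a block, peak thresholds, the overlap rule and the distance to gene starts.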

Results

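RNA-seq and ATAC-seq were measured in c-Kit-positive DN1 cells sorted after 7 days of culture on the Notch ligand-bearing stroma, with 2 control and 2 Tcf7/Lef1 knockout libraries per assay. The control RNA libraries listed 13188 and 13314 genes at 1 TPM or more, and the knockout libraries 13134 and 13050. The correlation of log2(TPM + 1) across genes was 0.983 between the control libraries, 0.983 between the knockout libraries and 0.943 to 0.947 between genotypes; genes are not independent replicates. The ATAC lists held 103009 and 105227 peaks in control and 109380 and 111007 in knockout outside the mitochondrial chromosome.

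The deleted genes were examined first. Tcf7 (chromosome 11, 52252283 to 52283014, mm10), which encodes TCF1, fell from 514 ± 6.3 TPM (SD, n = 2) in control to 12.8 ± 0.59 TPM in knockout, a 40.1-fold difference (log2 change −5.22, SE 0.056, adjusted p = 8.64e-06). It stood at 518 and 510 TPM in the control libraries and at 13.2 and 12.4 TPM in the knockout libraries. Lef1 (chromosome 3, 131110297 to 131224357) stood at 1.38 ± 0.40 TPM in control and 1.51 ± 0.077 TPM in knockout and did not pass the test (adjusted p = 0.80). Lef1 RNA was therefore near the floor in both genotypes, and its level does not check the Lef1 deletion.

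The study asked what TCF1 and LEF1 do at the start of T-cell fate, and the RNA comparison addresses which genes differed between control and knockout DN1 sorts. A difference can come from a changed mix of cells in the libraries as well as from changed expression within DN1 cells. The deepest falls were in the T-lineage genes Il2ra and Cd3g. Il2ra, the alpha chain of the interleukin-2 receptor (CD25), fell from 134 ± 1.9 to 0.525 ± 0.19 TPM, 256-fold (chromosome 2, 11642792 to 11693194), in cells that were gated as CD25-negative in both genotypes. Cd3g, a subunit of the T-cell receptor complex, fell from 94.1 ± 8.3 to 0.705 ± 0.51 TPM, 133-fold (chromosome 9, 44969572 to 44980431). In the opposite direction, Adipoq, the adipocyte hormone adiponectin, rose 22.9-fold from 1.23 ± 0.50 to 28.1 ± 3.1 TPM, and the mast cell protease Mcpt1 rose 6.95-fold from 14.6 ± 2.5 to 101 ± 1.3 TPM.

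The 10 largest falls were in Il2ra, Cd3g, Tcf7, Ctse (cathepsin E), Adm (the peptide hormone adrenomedullin), Atf3 (a stress-induced transcription factor), Cxcl1 (a neutrophil-attracting chemokine), Fgf3 (a fibroblast growth factor), the adhesion receptor Adgrg5 and Fam169b. Of these, Fgf3 fell from 149 ± 3.5 to 11.97 ± 0.75 TPM, Ctse from 52.5 ± 1.6 to 2.54 ± 0.25 TPM and Adm from 26.3 ± 2.5 to 1.16 ± 0.29 TPM. The 10 largest rises were in Adipoq, the mast cell proteases Cma1, Mcpt2 and Mcpt1, Plin1 (a lipid droplet coat protein), Gpm6b, Slc26a7 (an anion exchanger), Hdc (the enzyme that makes histamine), Agt (angiotensinogen) and Tmem178. Hdc rose from 9.09 ± 1.1 to 65.2 ± 1.1 TPM and Plin1 from 0.659 ± 0.22 to 10.6 ± 2.2 TPM. Cma1 was listed at 0 in the first control library and at 2.13 TPM in the second, against 12.7 and 14.9 TPM in knockout, and its call was lost without knockout replicate 2 (adjusted p = 0.051; 0.0022 to 0.045 under its other alternatives).

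Across 13228 tested genes, 1940 were lower and 3331 higher in knockout (limma, adjusted p under 0.05), of which 509 lower and 474 higher genes changed by at least 1 on the log2 scale. The split depended on scaling: 36.8% of calls were lower as deposited, 46.8% after quantile normalization (2296 lower, 2608 higher) and 50.6% after median-ratio scaling (2512 lower, 2451 higher). The median log2 change of all genes was 0.093 as deposited and −0.0030 after median-ratio scaling. The counts were 1088 lower and 2018 higher without control replicate 1, 1128 and 2025 without control replicate 2, 1418 and 2005 without knockout replicate 1, and 1450 and 2242 without knockout replicate 2.

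**Figure D1:**
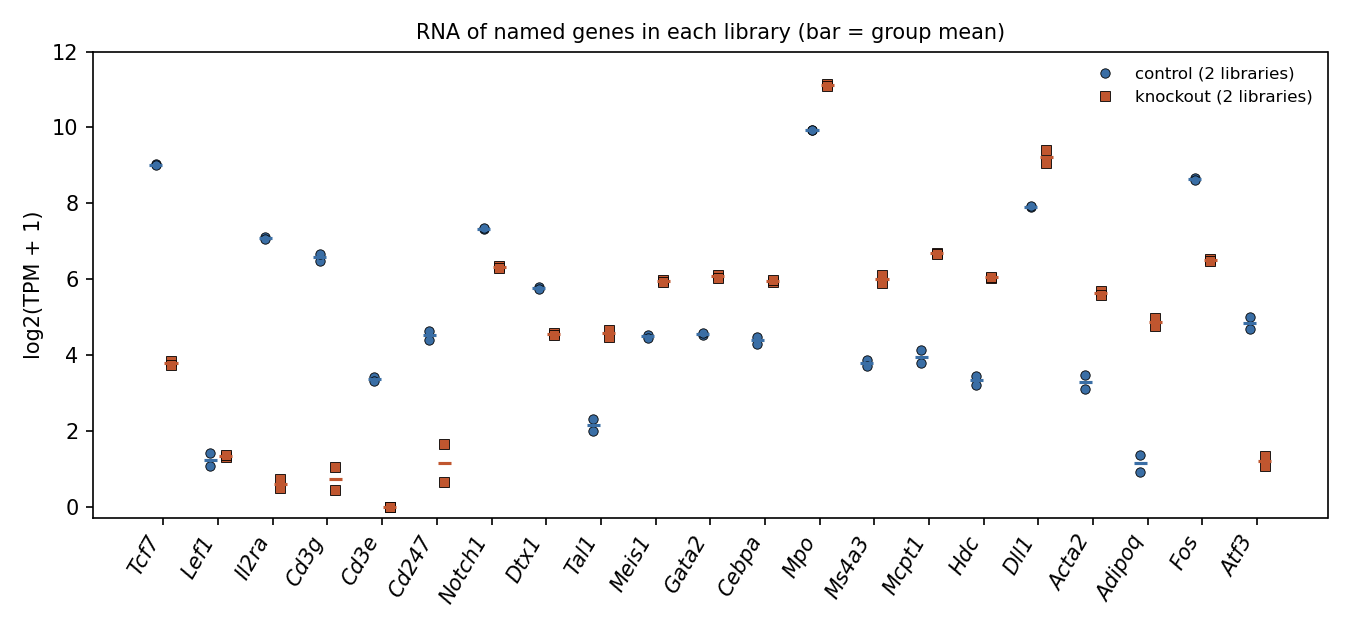
RNA of 21 named genes in each library, as log2(TPM + 1) on the vertical axis; circles are the 2 control and squares the 2 knockout libraries, and short bars are group means. Tcf7, Il2ra, Cd3g, Cd3e and Cd247 are lower in both knockout libraries, Lef1 is near 1.4 TPM in both genotypes, and Mcpt1, Hdc, Dll1 and Adipoq are higher in both knockout libraries.

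Genes of the T lineage fell together. Of 22 tested members of the T-lineage list, 20 fell, 0 rose and 2 did not pass (Cd6 and Tcf12, looked up afterwards), with a median log2 change of −2.06; adjusted over the list alone, 21 fell. Cd3e, another subunit of the T-cell receptor complex, stood at 9.69 and 8.995 TPM in control and was listed at 0 in both knockout libraries, and Cd247, the CD3 zeta chain, fell from 22.0 ± 2.8 to 1.37 ± 1.1 TPM. Among members singled out after their values were seen, Bcl11b, a transcription factor of T-cell commitment, fell from 8.73 ± 0.81 to 0.286 ± 0.068 TPM, Gata3, a transcription factor of early T cells, from 44.4 ± 1.4 to 9.67 ± 0.81 TPM, and Thy1 and Dntt, a surface marker and the DNA polymerase of antigen receptor rearrangement, had log2 changes of −2.97 and −2.07. Camera gave an adjusted p of 5.33e-15 for the list, and adjusted p = 0.167 with an estimated correlation. No list was called with an estimated correlation, a form that had little power with 2 residual degrees of freedom. Its misses therefore do not show that a list was unchanged.

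Notch target genes fell in part. Of 10 tested members, 7 fell, 0 rose and 3 did not pass (the same adjusted over the list alone; camera adjusted p = 5.62e-05; adjusted p = 0.167 with an estimated correlation). Il2ra belongs to this list as well. Notch1, the receptor itself, fell from 160 ± 1.7 to 78.3 ± 1.8 TPM, Dtx1, a Notch pathway ubiquitin ligase, from 53.4 ± 2.0 to 22.6 ± 0.60 TPM and Gpr183, an oxysterol receptor, from 22.3 ± 1.5 to 7.40 ± 1.1 TPM. Hes5, Nrarp and Myc, the members that did not pass, looked up afterwards, had log2 changes of −0.51, −0.12 and 0.13. The knockout libraries held more RNA of Dll1, the Notch ligand that the monolayer carries, at 603 ± 97 TPM against 238 ± 3.5 TPM in control.

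Stem and progenitor genes moved in both directions. Of 22 tested members, 10 rose, 7 fell and 5 did not pass, the same numbers adjusted over the list alone (camera adjusted p = 0.57; adjusted p = 0.61 with an estimated correlation). The largest changes were rises of transcription factor genes: Tal1 rose from 3.47 ± 0.70 to 22.8 ± 2.3 TPM, Hoxa9 from 4.52 ± 0.056 to 16.1 ± 1.1 TPM, Gata2, which the mast cell list shares, from 22.4 ± 0.80 to 66.1 ± 2.4 TPM and Meis1 from 21.5 ± 0.84 to 61.0 ± 1.7 TPM. Kit, the receptor used for the sort and named after its value was seen, was among the falls, with a log2 change of −0.64. The other falls, looked up afterwards, were the transcription factor genes Gfi1b, Nfe2, Erg, Hhex and Lyl1 (log2 changes of −0.77, −0.51, −0.50, −0.40 and −0.39) and Cd93 (−0.49).

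Myeloid genes also moved in both directions, with granule genes of neutrophils among the rises. Of 23 tested members of the myeloid list, 10 rose, 4 fell and 9 did not pass (the same adjusted over the list alone; camera adjusted p = 0.53; adjusted p = 0.61 with an estimated correlation). Mpo, the myeloperoxidase of neutrophil granules, rose from 980 ± 1.0 to 2226 ± 42 TPM, the granule protease Prtn3 from 110 ± 8.2 to 247 ± 0.27 TPM, Ms4a3, a marker of granulocyte and monocyte progenitors, from 12.8 ± 1.2 to 63.4 ± 6.6 TPM and Cebpa, a transcription factor of granulocyte fate, from 20.03 ± 1.9 to 60.9 ± 1.0 TPM. The 4 falls, looked up afterwards, were Irf8, Ccr2, Csf2ra and Itgam, with log2 changes of −0.23, −0.37, −0.45 and −0.61. The monocyte and macrophage genes Csf1r and Lyz2, picked after their values were seen from the 9 members that did not pass, had log2 changes of −0.13 and 0.05.

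Mast cell and basophil genes rose together. Of 12 tested members, 10 rose, 1 fell (Cpa3) and 1 did not pass (Mitf), both looked up afterwards, with a median log2 change of 1.97 and the same numbers adjusted over the list alone (camera adjusted p = 0.000166; adjusted p = 0.167 with an estimated correlation). Prss34, a basophil protease, rose from 5.24 ± 1.2 to 36.1 ± 0.059 TPM beside Mcpt1, Hdc and Cma1. Cpa3, mast cell carboxypeptidase, was abundant in both genotypes and had a log2 change of −0.33. Of 11 tested erythroid and megakaryocyte genes, 3 rose, 1 fell and 7 did not pass (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.16; adjusted p = 0.44 with an estimated correlation). Pf4, platelet factor 4, rose from 29.1 ± 4.4 to 68.7 ± 2.3 TPM, Car2, a carbonic anhydrase, rose from 91.3 ± 3.2 to 151 ± 0.064 TPM, and Itga2b, a platelet integrin, fell from 95.6 ± 2.1 to 51.7 ± 4.2 TPM.

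The NK and innate lymphoid, dendritic cell and B-lineage lists held more falls than rises, and the gamma-delta T list was not called. Of 12 tested NK and innate lymphoid genes, 8 fell, 1 rose and 3 did not pass (8 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.000505; adjusted p = 0.167 with an estimated correlation). The granzymes Gzmb and Gzma fell from 515 ± 12 to 195 ± 5.6 TPM and from 130 ± 5.4 to 36.5 ± 0.95 TPM, Cd160 fell from 17.2 ± 3.2 to 2.02 ± 0.20 TPM, and Il1rl1, the interleukin-33 receptor, which the mast cell list shares, rose from 2.78 ± 0.51 to 10.3 ± 1.4 TPM. Of 14 tested dendritic cell genes, 7 fell, 1 rose and 6 did not pass (the same adjusted over the list alone; camera adjusted p = 0.000348; adjusted p = 0.299 with an estimated correlation). The MHC class II genes H2-Eb1 and H2-Aa had log2 changes of −0.94 and −0.75. Of 6 tested B-lineage genes, 4 fell, 1 rose and 1 did not pass (the same adjusted over the list alone; camera adjusted p = 0.0318; adjusted p = 0.324 with an estimated correlation). This call was also lost without knockout replicate 2 (adjusted p = 0.124), with a mean TPM of at least 5 (0.678) and without the filter on low values (0.126; 0.124 to 0.678 over the alternatives that ended it). Cd72, a B-cell surface receptor, fell from 69.4 ± 4.7 to 24.5 ± 0.35 TPM. Ebf1, a transcription factor of B-cell fate that stromal cells also express, rose from 3.80 ± 0.24 to 13.9 ± 1.8 TPM. Of 6 tested gamma-delta T genes, 3 fell, 1 rose and 2 did not pass (the same adjusted over the list alone; camera adjusted p = 0.18; adjusted p = 0.61 with an estimated correlation). Sox4 fell from 368 ± 3.4 to 206 ± 1.1 TPM, Blk and Cd163l1 had log2 changes of −1.63 and −1.55, and Etv5 rose by 1.68.

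Stromal genes, the markers of the culture monolayer, rose in the knockout libraries. Of 14 tested members, 11 rose, 0 fell and 3 did not pass, with a median log2 change of 1.04 (12 rose adjusted over the list alone; camera adjusted p = 0.000166; adjusted p = 0.324 with an estimated correlation). Beside Dll1, the contractile gene Acta2 rose from 8.85 ± 1.8 to 48.4 ± 2.4 TPM, Mgp (matrix Gla protein) from 6.07 ± 0.89 to 22.5 ± 0.65 TPM and Postn (periostin) from 0.498 ± 0.064 to 7.32 ± 0.62 TPM. These rises stood beside those of the mast cell genes, and of some stem and myeloid genes, in the same libraries.

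Cell cycle genes rose by small amounts. Of 20 tested members, 17 rose, 0 fell and 3 did not pass, with a median log2 change of 0.57 (17 adjusted over the list alone; camera adjusted p = 9.18e-05; adjusted p = 0.167 with an estimated correlation). The replication helicase genes Mcm2 and Mcm5 rose from 131 ± 1.7 to 227 ± 4.1 TPM and from 126 ± 8.5 to 202 ± 6.0 TPM. Ccne1 and Ccne2, cyclins of the entry into DNA replication, rose by 0.64 and 0.97 on the log2 scale. The Ccne1 call was lost without each of control replicates 1 and 2 and knockout replicates 1 and 2 (adjusted p = 0.051 to 0.10), and the Ccne2 call without knockout replicate 1 or 2 (adjusted p = 0.072 and 0.062).

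Handling stress genes, chosen because cell dissociation induces them, mostly fell. Of 14 tested, 11 fell, 2 rose and 1 did not pass (the same adjusted over the list alone; camera adjusted p = 1.52e-05; adjusted p = 0.167 with an estimated correlation). The immediate-early genes fell, with Fos going from 396 ± 6.7 to 89.9 ± 2.2 TPM, Dusp1 from 162 ± 5.7 to 48.7 ± 0.15 TPM and Ier3 from 49.3 ± 0.21 to 13.4 ± 1.3 TPM. The risen members, looked up afterwards, were the chaperone genes Hspa8 and Hsp90aa1.

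Camera called none of the p53, Wnt and interferon lists. Of 15 tested p53 target genes, 7 rose, 2 fell and 6 did not pass (8 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.48; adjusted p = 0.61 with an estimated correlation); Phlda3, Zmat3, Aen and Ccng1 rose 3.75-fold, 3.21-fold, 2.37-fold and 2.09-fold. Of 6 tested Wnt target genes, the textbook readout of TCF/LEF activity, 2 fell, 1 rose and 3 did not pass (2 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.63; adjusted p = 0.67 with an estimated correlation). Axin2 stood at 2.84 ± 0.57 and 1.18 ± 0.17 TPM and Rnf43 at 3.33 ± 0.95 and 1.18 ± 0.17 TPM in control and knockout. Without each of control replicates 1 and 2 and knockout replicates 1 and 2 in turn, both calls were lost (adjusted p = 0.079 to 0.16 for Axin2 and 0.052 to 0.13 for Rnf43). Without the filter on low values both were lost as well (adjusted p = 0.082 and 0.064), and the Axin2 call also with a pseudocount of 0.1 (0.053) and quantile normalization (0.056). Ccnd1, cyclin D1, rose from 18.1 ± 1.3 to 43.8 ± 2.5 TPM. Of 16 tested interferon response genes, 3 rose, 1 fell and 12 did not pass (1 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.63; adjusted p = 0.67 with an estimated correlation), with a median log2 change of −0.06 and a mean of 0.06, camera's direction being down; Ifit1 rose from 2.43 ± 0.17 to 6.93 ± 0.16 TPM. The call of Rsad2 was lost without any one of the 4 libraries (adjusted p = 0.082 to 0.17), and that of Ifit3 without control replicate 1 or either knockout replicate (adjusted p = 0.11 to 0.12). Both were also lost without the filter on low values (adjusted p = 0.098 and 0.075), and that of Ifit3 with median-centred changes (0.051).

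Of 149 called members of the 16 lists, 7 lost their call after quantile normalization and 5 after median-ratio scaling.

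**Figure D2:**
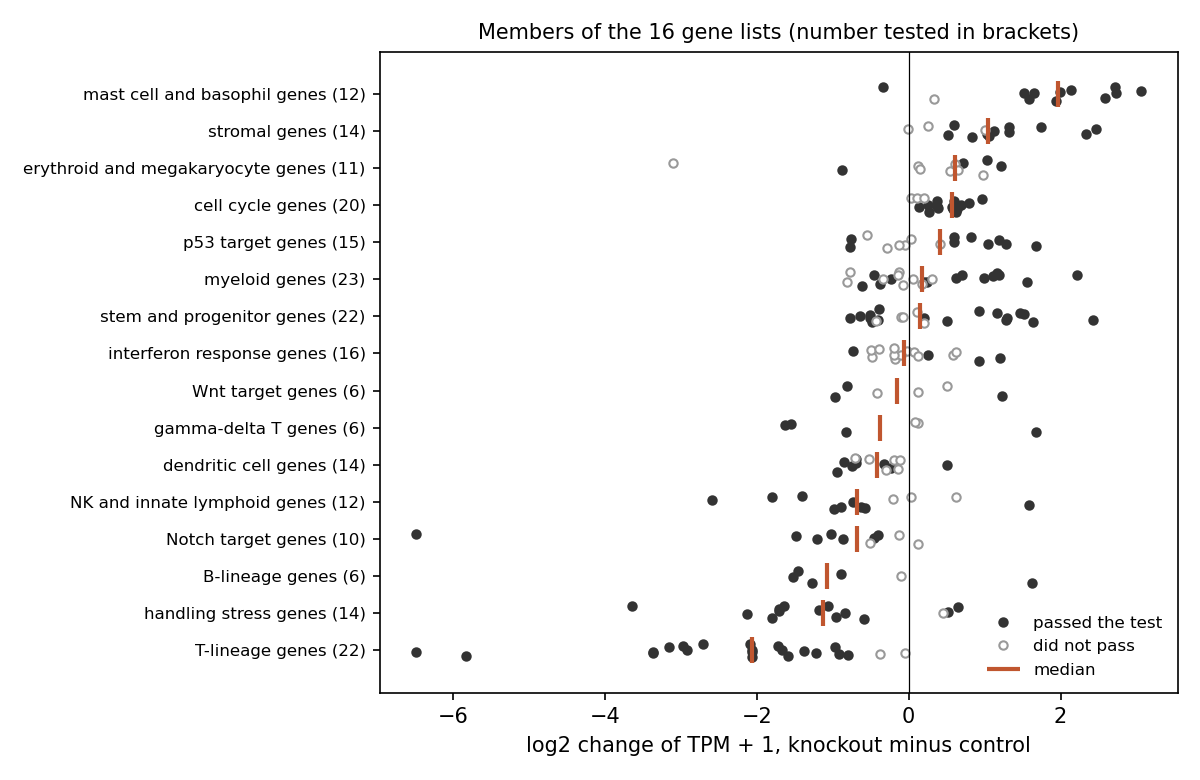
Log2 change of TPM + 1, knockout minus control, on the horizontal axis for each tested member of the 16 gene lists, ordered by median; filled points passed the test, open points did not, and vertical bars are medians. The T-lineage median is −2.06 and the mast cell and basophil median 1.97, with 20 of 22 and 11 of 12 members passing the test.

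The ATAC comparison addresses where chromatin was open in one genotype and not in the other. The strongest control-alone region lay inside Foxn3 (chromosome 12, 99329131 to 99329626, mm10), a forkhead transcription factor gene, with a −log10 q of 194 in both control lists and no peak in either knockout list. The next control-alone regions by the lower of the replicates' −log10 q each lay inside a gene and had as the nearest gene start that of Aldh1a3 (chromosome 7, 66416524 to 66417092), Mast2 (chromosome 4, 116443426 to 116443868), St18 (chromosome 1, 6519091 to 6519556) or Ccdc167 (chromosome 17, 29693605 to 29693972). The strongest knockout-alone regions were nearest to Phf20 (chromosome 2, 156210764 to 156211136), Rnf216 (chromosome 5, 143106921 to 143107350), Cd5l (chromosome 3, 87330778 to 87331170), Sec24b (chromosome 3, 130090317 to 130090750) and Mir99a (chromosome 16, 77499833 to 77500286), with a −log10 q of up to 81.9. None of these 10 nearest genes was called in the RNA comparison; Aldh1a3, St18, Cd5l and Mir99a were too low to be tested. Peak scores are the authors' and rank peaks within a list only.

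Of 134830 union regions, 6458 (4.79%) were open in control alone, 8939 (6.63%) in knockout alone and 79684 (59.1%) in all 4 libraries. The pairs of a control with a knockout library gave 1042 to 1348 such regions. Genotype-specific regions lay at gene starts less often: 3.84% of control-alone and 6.41% of knockout-alone regions were within 1 kb of a gene start, against 18.2% of regions open in all 4 (Fisher's exact test, two-sided, p = 1.51e-254 and 1.47e-211). Regions are not independent replicates. Regions open in all 4 were also wider, with a median of 365 bp against 240 and 229 bp. Regions of the mixed pairs were not compared, so this contrast may hold for any region missing from some lists. The knockout lists were longer, and with the 50000 strongest peaks of each list the order turned, with 3889 control-alone and 3401 knockout-alone regions. Without control replicate 1 or 2 the control-alone number was 11111 or 10247, and without knockout replicate 1 or 2 the knockout-alone number was 16282 or 15400, since a group that rests on 1 list keeps peaks that its replicate lacks.

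**Figure D3:**
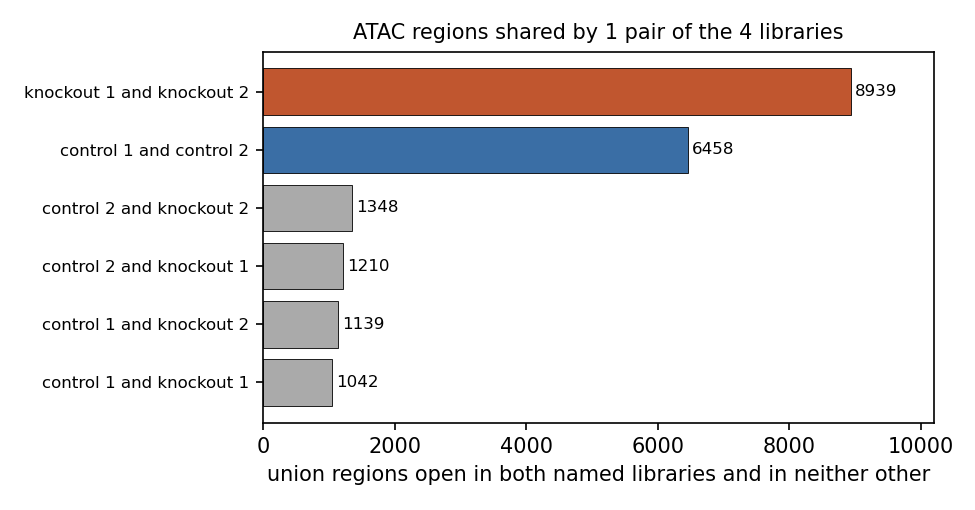
Number of union regions open in both libraries of a pair and in neither of the others, on the horizontal axis, for each of the 6 pairs of ATAC libraries. The pair of knockout libraries shares 8939 regions and the pair of control libraries 6458, against 1042 to 1348 for pairs that mix the genotypes.

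Control-alone regions lay at the deleted gene and at 12 of 22 tested T-lineage genes, against 17.7% of all tested genes, and knockout-alone regions at 8 of the 22, against 23.8%. Among genes with like numbers of regions 6.66 and 8.32 were expected, and neither count passed the permutation test (adjusted p = 0.52 and 1). Those numbers include the regions under test, so the permutation cannot say that region number alone explains the counts. Tcf7 had 6 control-alone regions and 1 knockout-alone region among 17 assigned to it, the most control-alone regions of any tested gene. The strongest lay inside the gene (52262025 to 52262297, −log10 q of at least 46.6), and the weakest had a lower −log10 q of 7.30, 6.37 and 6.16. Tcf7 is itself floxed, so peaks in excised DNA would be lost whatever the chromatin state, and which DNA is excised was not examined. Of the T-lineage genes named by rule, Cd247 had 3 control-alone regions among 13, Cd3g had 1 of 1 and Il2ra 1 of 13, Cd3e had 0 of 6, and none of these had a knockout-alone region. Several lay at gene starts: the Cd3g region (chromosome 9, 44980297 to 44980592) was centred 14 bp from the Cd3g start, a Cd247 region (chromosome 1, 165788579 to 165788826) 22 bp from the Cd247 start and, noted after its value was seen, a Thy1 region (chromosome 9, 44043215 to 44043558) 3 bp from the Thy1 start. Their lower −log10 q was 13.9, 7.43 and 11.5, against medians of 22.6 and 22.8 in the control lists. Thy1 also had 1 knockout-alone region, and Gata3, looked up afterwards, had 2 knockout-alone and 0 control-alone regions among 8. Regions open in all 4 libraries were 7 of 13 at Il2ra, 5 of 13 at Cd247, 3 of 6 at Cd3e, 0 of 1 at Cd3g and 7 of 14 at Thy1, against 59.1% of all union regions. Of the myeloid genes named by rule, Ms4a3 and Mpo each had 1 knockout-alone region and 0 control-alone regions, among 4 and 7, and Cebpa and Prtn3 had neither, among 11 and 3.

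**Figure D4:**
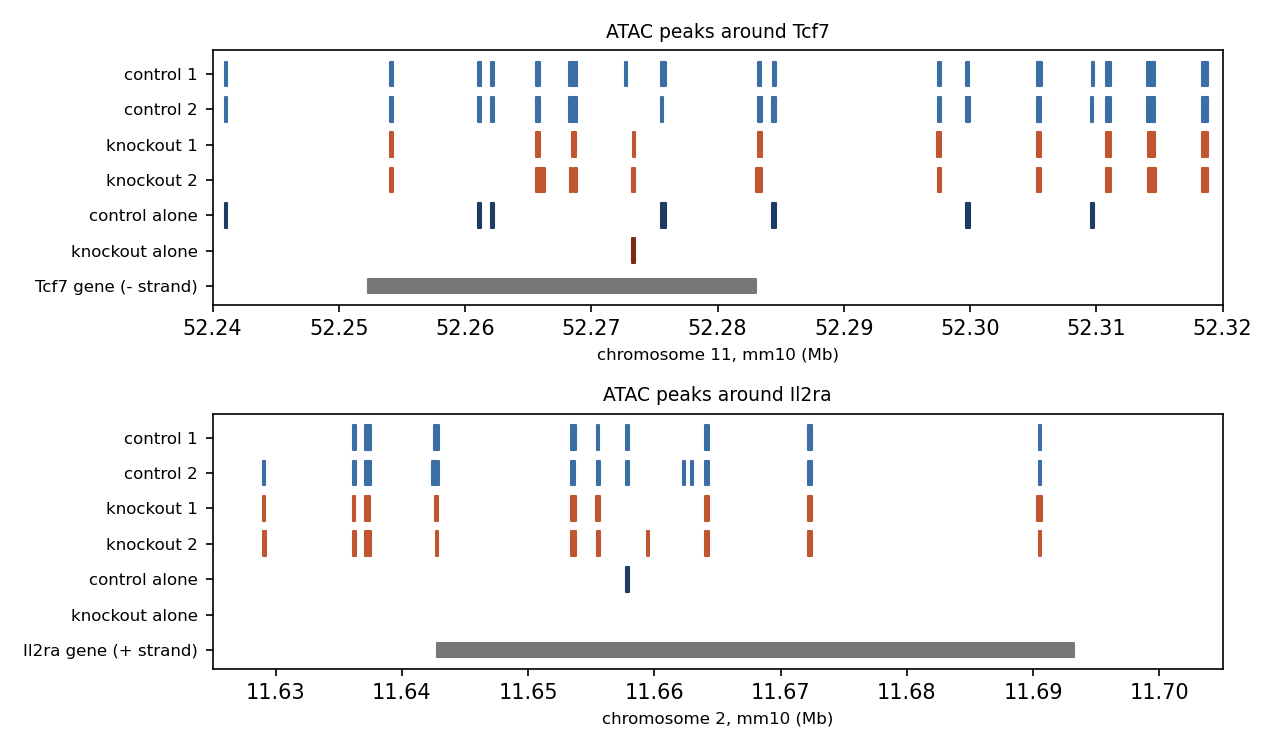
ATAC peaks of the 4 libraries along 80 kb around Tcf7 on chromosome 11 and around Il2ra on chromosome 2 (horizontal axis, mm10 position in Mb), with the regions open in control alone or in knockout alone and the span of the gene. Of the 17 regions assigned to Tcf7, 6 are open in control alone and 1 in knockout alone. Of the 13 assigned to Il2ra, 1 is open in control alone and 0 in knockout alone.

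The last comparison addresses whether genes that changed in RNA lie near regions that changed in ATAC. Genes that fell carried control-alone regions more often than genes that rose: 514 of 1940 (26.5%) against 482 of 3331 (14.5%), an odds ratio of 2.13 (Fisher's exact test, two-sided, adjusted p = 2.22e-25). Against the 7957 genes not called, of which 1349 (16.95%) had such a region, the odds ratio for fallen genes was 1.77 (adjusted p = 3.82e-20) and for risen genes 0.829 (adjusted p = 0.00126). Knockout-alone regions lay near 854 of the risen genes (25.6%), 504 of the fallen genes (26.0%) and 1784 of those not called (22.4%), so that both risen and fallen genes exceeded genes not called (odds ratios 1.19 and 1.21, adjusted p = 0.000508 and 0.00126) and no difference between them passed the test (odds ratio 0.982, adjusted p = 0.79).

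Fallen genes had a mean of 7.08 assigned regions of any kind, against 4.86 for risen genes and 4.86 for genes not called. Permuting labels among genes with like numbers of regions changed these results. Those numbers include the control-alone and knockout-alone regions under test. The strata therefore also remove part of any difference in them, and cannot decide what region number alone explains. Fallen genes then carried 1.04 times the expected number of control-alone regions relative to genes not called, which no longer passed (adjusted p = 0.24), but still 1.10 times that expected relative to risen genes (adjusted p = 0.0003). Within these strata knockout-alone regions went with the direction of the RNA: risen genes had 1.14 times the expected number relative to fallen genes, and fallen genes 0.852 times that expected relative to genes not called (both adjusted p = 6e-05, from the smallest p that 100000 permutations can give, 2e-05). Control-alone regions also raise a gene's stratum, which by itself can lower the ratio of knockout-alone regions near fallen genes. Genes are not independent replicates, and these tests describe these lists. The risen, fallen and not called genes are those of the TPM as deposited. After median-ratio scaling 2451 of the 3331 risen genes kept their call and 2512 genes were lower. The link tests were not repeated with those calls, so odds ratios close to 1 may depend on the scaling.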

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

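The test in this part was chosen after the data were seen. Peaks on the mitochondrial chromosome, which the comparisons left out, covered 10631 and 10642 bp of that chromosome in the knockout ATAC libraries (mean 10636.5 bp) and 10167 and 10019 bp in the control libraries (mean 10093 bp). They fell into 8 and 7 peaks in knockout and 12 and 11 peaks in control. The item stands here because its level in knockout lay above that in control, and no explanation was tested.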

How the results depend on the processing

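The alternatives in this part were planned, except TPM without Rpph1 and median-centred changes, chosen after the data were seen. Requiring a log2 change of at least 1 left 509 lower and 474 higher genes. Leaving out 1 library gave 1088 to 1450 lower and 2005 to 2242 higher genes, where the lone library was assumed to vary like the other group. Without Rpph1 the counts were 2310 and 2731, and after median-centring 2486 and 2476. The replicate numbers pair nothing in the labels; with the replicate number as a block, 1798 genes were lower and 3072 higher, and same-numbered libraries did not deviate together (r = 0.0043 across genes, which are not independent replicates). Axin2 and Rsad2 were among the named genes whose call was lost under the block (adjusted p = 0.078 and 0.074). Of 77 named genes, 76 were called, 0 changed sign and 11 lost the call under some alternative, 5 of these without a library being left out. Of 16 gene lists, 9 were called with the preset correlation and 15 with fry. With an estimated correlation 0 were called, where 2 residual degrees of freedom left little power. Fry tests whether a list's genes move one way on balance and makes no comparison with other genes. Its direction was up for the Wnt target and interferon lists, where camera's was down. With the 50000 strongest peaks of each list, 3889 regions were open in control alone and 3401 in knockout alone, fewer because fewer peaks entered. Leaving out 1 ATAC library gave 8682 to 11111 and 12421 to 16282. Permutation within strata of regions per gene gave 1.0361 times the expected number of control-alone regions near fallen genes, against genes not called, which no longer passed. It gave 1.141 times that of knockout-alone regions near risen against fallen genes, which then passed, and 0.8515 times near fallen genes against genes not called, a reversal. The strata remove the different number of regions per gene, which counts the tested regions too, so these changes cannot be laid to region number alone. The search for TCF/LEF motifs and its alternatives were not run. Depth limits low genes such as Lef1, and ATAC depth is unknown.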

Other observations

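The 4 gene lists, the tests of lists against regions and the tests of explanations in this part were all chosen after the results were seen. Genes of the hypoxia response fell: of 24 tested members, 21 fell, 0 rose and 3 did not pass. Bnip3, a mitophagy receptor, fell from 128 ± 7.1 to 28.3 ± 2.7 TPM (SD, n = 2), Vegfa, the vascular growth factor, from 68.2 ± 1.4 to 19.6 ± 0.30 TPM, and Egln3, an oxygen-sensing prolyl hydroxylase, from 142 ± 9.1 to 48.6 ± 0.61 TPM. Over the 21 members whose values had not been seen, 18 fell (camera adjusted p = 2.67e-11; adjusted p = 0.079 with an estimated correlation). NF-kappaB target genes fell in 16 of 19 cases, with 0 rising. Tnfaip3, a feedback inhibitor of the pathway, fell from 52.9 ± 3.5 to 9.92 ± 2.2 TPM, and the chemokine gene Ccl4 from 60.9 ± 1.6 to 10.2 ± 0.21 TPM. Over 16 unseen members, 13 fell (camera adjusted p = 9.58e-10; adjusted p = 0.079 with an estimated correlation).

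Ribosome biogenesis genes rose by small amounts in 20 of 20 cases, with a median log2 change of 0.68 (camera adjusted p = 8.75e-08; adjusted p = 0.079 with an estimated correlation). Ncl, nucleolin, rose from 695 ± 0.70 to 1023 ± 15 TPM and Bop1, a processing factor of the large subunit, from 28.5 ± 2.2 to 59.0 ± 5.8 TPM. Of 11 tested adipocyte genes, 8 rose, 0 fell and 3 did not pass. Over 7 unseen members, 4 rose (camera adjusted p = 0.00698; adjusted p = 0.109 with an estimated correlation). Lpl, lipoprotein lipase, rose from 15.7 ± 1.3 to 67.1 ± 8.8 TPM and Fabp4, a fatty acid binding protein, from 45.9 ± 6.1 to 149.6 ± 1.9 TPM. Regions open in knockout alone were centred 88 bp from the start of Plin1, 68 bp from that of Fabp4 and 434 bp from that of Agt. Fabp4 also had a control-alone region 3301 bp from its start. Of 22 tested T-lineage genes, 12 had a control-alone region, against 17.7% of all tested genes (odds ratio 5.59, Fisher's exact test, two-sided, adjusted p = 0.00415 over 40 tests). Among genes with like numbers of regions 6.66 were expected, and the call ended (permutation test, unadjusted p = 0.017, adjusted p = 0.52). Those numbers count the control-alone regions too, so the end of the call does not show that region number explains the excess.

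Stromal and adipocyte genes were higher in knockout, and OP9 cells, from which the monolayer derives, are a candidate source, although the sort for c-Kit should remove them. Stromal RNA was not confined to the knockout. In control, Dll1, the ligand that the monolayer carries, stood at 238 TPM, Cxcl12 at 236, Fn1 at 210 and Col1a2 at 83.6 TPM, while Lum and Dcn stood at 0. Dll1 and Cxcl12 each rose by 1.32 on the log2 scale in knockout. A lower share of sorted progenitors that raised every other cell type alike would raise the dendritic cell list too. That list had a median log2 change of −0.42 (SD over members 0.38) against 1.04 for the stromal list. Of the dendritic cell list, Siglech, Xcr1 and Cd209a were too low to be tested, while Flt3, Irf8 and Bst2 also stand on other lists, Flt3 on that of stem and progenitor genes. Where progenitors supply part of this RNA, the list's median cannot decide on their share. These values also do not bear on a larger share of monolayer cells alone, which need not raise dendritic cell genes. More RNA of one unchanged stromal profile, as the only source of these genes, would move them together, but 8 of 13 other stromal members differed from Dll1 by more than 2 combined SE. Of these, 3 lay above it (Mgp, Postn and Acta2) and 5 below. Cxcl12, Col1a1, Col1a2, Sparc and Timp1 lay within that limit of Dll1. The test therefore speaks only against one unchanged profile for all members, and more monolayer RNA as part of the pattern is not excluded. What stays open is a larger share of monolayer cells, a monolayer whose state differed with the genotype on it, expression by the progenitors themselves, or a mix of these. Of 11 adipocyte members, 7 had a knockout-alone region (odds ratio 5.63, Fisher's exact test, adjusted p = 0.074, and stratified permutation, adjusted p = 0.53), but regions of monolayer cells would look alike.

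Mast cell and basophil genes were higher in knockout. Scaling of the libraries is argued against by its size: the median-ratio factors were 0.965 to 1.047, far too small to give a median log2 change of 1.97. After that scaling the median was 1.90 and 10 of 12 members were called higher, which such small factors could hardly have altered. A few mature mast cells or basophils in the knockout libraries could give these rises, and mast cells carry c-Kit, so the gate keeps them, while it should remove mature basophils, which carry little or none. Cpa3, with a log2 change of −0.33, does not exclude this, because its control level of 180 TPM, against a median of 4.79 TPM for the risen members, would hide a small share. No biological explanation was tested for this pattern.

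Over the 56 tested members of the handling stress, NF-kappaB and hypoxia lists, of which 47 were called lower, RNA was lower in knockout by a median of 1.01 on the log2 scale. Handling that differed from library to library within a genotype is argued against, since the median absolute difference between replicates over all 56 members was 0.0721. Handling or culture conditions that differed between the genotypes cannot be told apart from the knockout, as both follow the same split. Of 13 called handling stress genes, 2 were higher, the chaperone genes Hspa8 and Hsp90aa1, too few to exclude such handling. A fall of these genes through loss of TCF1 and LEF1 is therefore untested.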
